A study of Mus musculus with 10 samples.

How the data were processed

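Sperm DNA of F2 mice was profiled by RRBS in 5 control and 5 arsenic samples, grouped by the labels. Per the labels, sperm DNA was extracted with phenol and chloroform, purified with a column kit and made into sequencing libraries. The submitters' processing notes name Trim Galore 0.6.5, Bismark 0.22.3 and methylKit 1.22.0 and the mouse build mm10; settings are not given in the sources used here. The authors deposited a table of counts per CpG cytosine and sample: all reads, methylated reads and unmethylated reads. The counts carry no normalization. All reads equalled methylated plus unmethylated reads at each of the 1944166 cytosines, and each cytosine had at least 10 reads in every sample. Both strands were listed apart (971921 plus and 972245 minus cytosines) and kept apart. Among sites with even coverage and at least 5 methylated and 5 unmethylated reads, 67.8 to 70.7% had an even methylated count, where independent reads give about 50%. Reads without molecular identifiers are not independent molecules, so depth here counts reads.

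The methylation level of a site was methylated reads over all reads, in percent, and values per sample are means over sites unless stated. Windows and gene ends used summed reads. Single values per sample were compared by a two-sided exact permutation test over all 252 assignments of the 10 samples, whose smallest p is 0.00794, with 95% intervals from inverting the test. Sites, 1 kb windows and gene-end windows were tested by quasi-binomial logistic regression of methylated against unmethylated reads on group. The Pearson dispersion was moderated across features by the method of limma's squeezeVar and held at 1 or above, and p from the F test was adjusted by Benjamini-Hochberg. Sites needed a mean of 5 to 95% and were called at an adjusted p under 0.05 and a difference of 10 points. Windows and gene ends needed 3 cytosines and a mean of 2.5 to 97.5%, and were called at 5 points. Differences are arsenic minus control.

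The tests between groups given above, the gene lists and the regions were fixed before the data were examined, as were all but a few of the alternatives. Some tests of the additional observations were chosen later and are named there. The gene records used carry mm10 coordinates without strand or exons, and no genome sequence was used. Promoters were therefore replaced by windows at both ends of each record, from 1000 bp outside to 500 bp inside, a choice made before any gene-level value was seen. For lists and single genes the end with more covered cytosines stood for the gene. Named features were, in each direction, the 10 called features with the largest difference, or the 5 of smallest unadjusted p where fewer than 5 were called. From each list called members and up to 4 members of smallest p could be named. List and region tests were adjusted by Benjamini-Hochberg over 14 lists and 16 regions. Rn18s-rs5 stood for ribosomal DNA in place of another record. Exons, introns, repeats, Snrpn, Mest and Kcnq1ot1 were not analysed here, and the values of 1 list member are not reported here.

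The regression was checked against R's own functions and tested on simulated data with the coverage and dispersion of the real table, with 200 features changed per size. It called 7 unchanged sites, 13 unchanged windows and 14 unchanged gene ends. Alternatives were limma on the log2 ratio of methylated to unmethylated reads with 1 added to each, edgeR's quasi-likelihood test on windows, logistic regression with no overdispersion, dispersion of each feature alone, other limits of coverage, mean, window and difference, merged strands, autosomes, weighting by reads, a replicate block and leaving out each sample. The tests were repeated on 100 of the 126 splits of the samples into 5 and 5, the real one included. Software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and edgeR 4.0.16.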

Results

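DNA methylation was measured by reduced representation bisulfite sequencing (RRBS) in sperm of F2 mice. The method sequences CpG-rich restriction fragments after bisulfite treatment. The samples formed a control group and an arsenic group of 5 sperm samples each, and the series was designed to compare these groups. The labels give neither the arsenic dose nor the generation that received it, and they do not say whether each sample came from a separate animal. Both groups shared a table of 1944166 CpG cytosines, each covered by at least 10 reads in every sample. Reads summed over these cytosines ran from 73390422 in control 3 to 105850658 in control 1, and median coverage per sample from 28 to 45 reads. Median coverage averaged 37.4 ± 7.8 reads in control and 38.2 ± 4.87 in arsenic samples (SD, n = 5 each, two-sided exact permutation p = 0.833).

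Sperm DNA of both groups was split between largely unmethylated and largely methylated CpG sites, and no difference in mean level was detected. Sites with a mean under 20% made up 42.3% of the table and sites over 80% made up 47.8%. Over all cytosines the level was 52.1% ± 0.216 in control and 52.1% ± 0.143 in arsenic sperm (SD, n = 5 each, exact permutation p = 0.937). The difference of arsenic minus control was -0.0155 points, with a 95% interval from -0.264 to 0.264. Sites under 20% stood at 2.42% ± 0.167 in control and 2.41% ± 0.0961 in arsenic sperm (n = 5 each, exact permutation p = 0.968). Partly methylated sites, with means from 20 to 80%, stood at 53.8% ± 1.1 and 53.8% ± 0.717 (n = 5 each, exact permutation p = 0.952). Sites over 80% stood at 95.8% ± 0.123 and 95.8% ± 0.131 (n = 5 each, exact permutation p = 0.786).

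**Figure D1:**
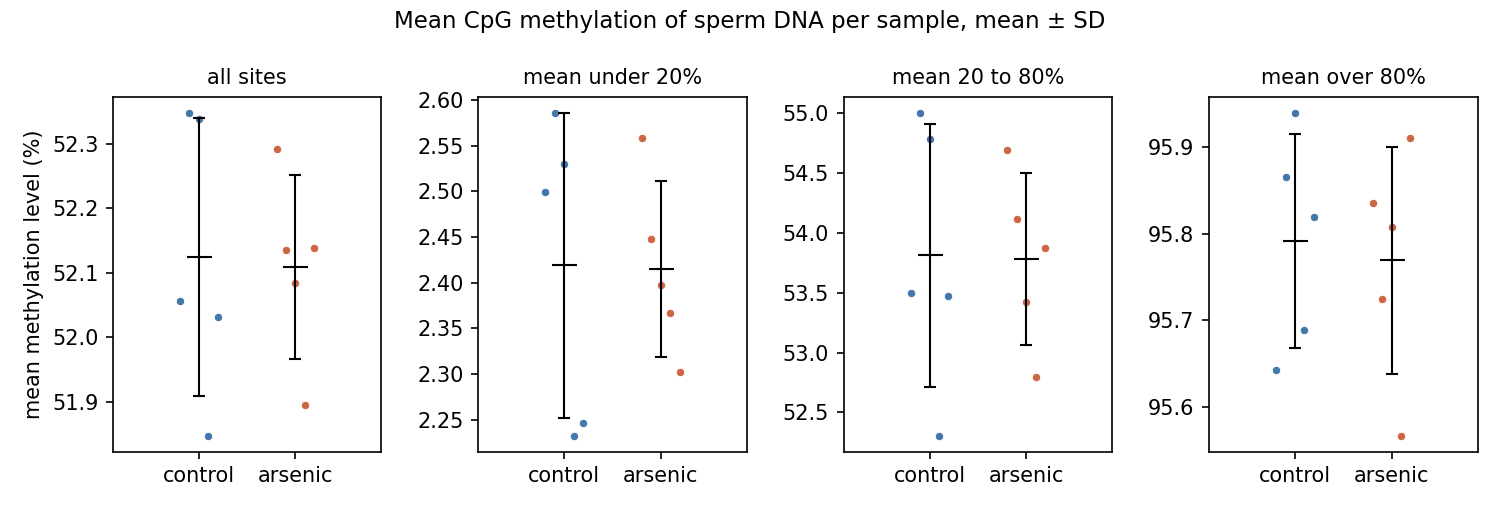
Mean methylation level in percent per sample, for all cytosines and for the 3 strata of site means, each with its own scale; points are samples, bars and whiskers the group mean and SD (n = 5). The groups overlap in every panel, with 52.1% over all sites in control and 52.1% in arsenic sperm.

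The sex chromosomes, the mitochondrial genome and gene records were compared in the same way. The X chromosome stood at 55.4% ± 0.261 in control and 55.4% ± 0.16 in arsenic sperm (n = 5 each, exact permutation p = 0.865). The Y chromosome stood at 59.7% ± 1.26 and 59.5% ± 0.644 (n = 5 each, exact permutation p = 0.762). The 15 mitochondrial cytosines stood at 2.15% ± 0.75 and 2.19% ± 0.74 (n = 5 each, exact permutation p = 0.937). Gene-end windows, from 1000 bp outside to 500 bp inside either end of a gene record, stood at 14.4% ± 0.155 in control and 14.4% ± 0.102 in arsenic sperm (n = 5 each, exact permutation p = 0.778). The rest of the gene records stood at 62.5% ± 0.208 and 62.4% ± 0.145 (n = 5 each, exact permutation p = 0.762), and cytosines outside gene records at 70.1% ± 0.301 and 70.1% ± 0.209 (n = 5 each, exact permutation p = 0.825). Levels were lower where covered CpG cytosines were dense. Windows of 1 kb with 3 to 9 covered cytosines averaged 78.4% ± 0.186 in control and 78.4% ± 0.128 in arsenic sperm (n = 5 each, exact permutation p = 0.992). Windows with 50 or more averaged 3.48% ± 0.162 and 3.45% ± 0.0987 (n = 5 each, exact permutation p = 0.714).

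**Figure D2:**
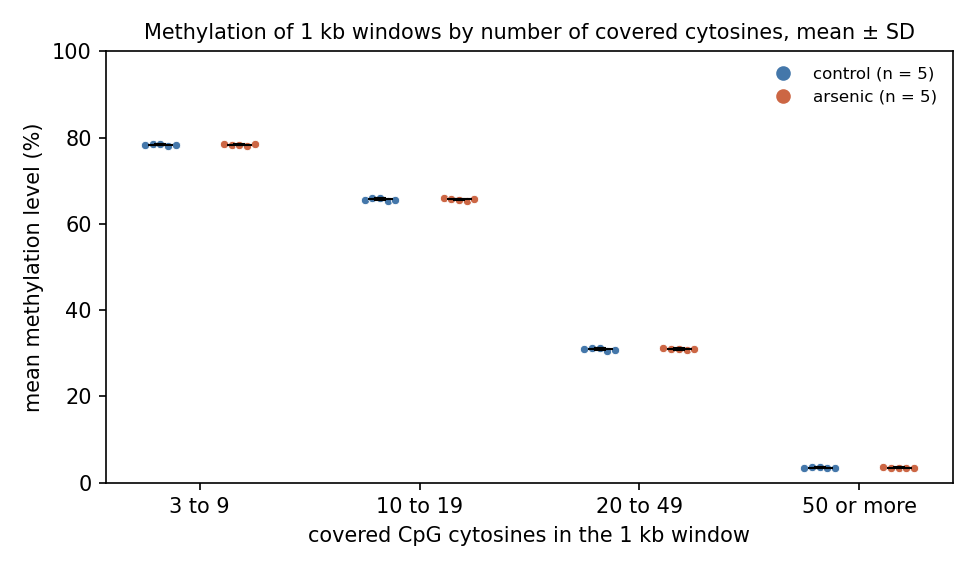
Mean methylation level in percent of 1 kb windows, grouped by the number of covered CpG cytosines; points are samples, bars and whiskers the mean and SD of each group (n = 5). Control levels run from 78.4% at 3 to 9 cytosines to 3.48% at 50 or more, with arsenic samples beside them at 78.4% and 3.45%.

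Imprinted regions methylated on the paternal allele were highly methylated in both groups, each read from few cytosines. The H19 imprinting control region (mm10 chromosome 7, 142579646 to 142583146), methylated on the paternal allele, stood at 98.4% ± 0.664 in control and 98.1% ± 1.35 in arsenic sperm from 4 cytosines (n = 5 each, exact permutation p = 0.667). The Dlk1-Meg3 intergenic region (chromosome 12, 109524996 to 109531996), also paternally methylated, stood at 98.1% ± 1.91 and 97.2% ± 1.61 from 5 cytosines (n = 5 each, exact permutation p = 0.397). The region upstream of Rasgrf1 (chromosome 9, 89876508 to 89882508) stood at 83.8% ± 0.76 and 82.3% ± 4.999 from 8 cytosines (n = 5 each, exact permutation p = 0.532). Reads behind these regions ran from 97 to 436 per sample. The higher-coordinate end of the H19 record itself was partly methylated, at 57.9% ± 8.87 and 59.1% ± 7.07 (n = 5 each, exact permutation p = 0.849), and the lower end stood at 96.9% ± 1.01 and 96.97% ± 1.3 (n = 5 each, exact permutation p = 0.937).

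Of the 19 measured imprinted genes methylated on the maternal allele, 18 averaged under 20% in sperm, and 1, Fkbp6, named after its value was seen, averaged 86.4% ± 2.28 (SD, n = 10). For comparison, 84.4% of the cytosines in all gene-end windows had a mean under 20%. The windows of these genes hold 17 distinct sets of cytosines, since Peg10 shares its set with Sgce and Peg3 with Usp29. The higher end of Grb10, a growth factor receptor adaptor, stood at 0.643% ± 0.306 in control and 0.826% ± 0.268 in arsenic sperm over 133 cytosines (n = 5 each, exact permutation p = 0.341). Whether this and the other gene ends cover the maternally methylated region of their gene was not tested, so a low level there need not reflect imprinting. Airn, the antisense transcript of Igf2r, stood at 1.35% ± 1.63 and 1.34% ± 1.1 (n = 5 each, exact permutation p = 0.992). The lower end of Zrsr1 (chromosome 11, 22971005 to 22972505) stood at 1.69% ± 0.483 and 3.65% ± 1.48, with adjusted p = 0.317 over 16 regions (n = 5 each, exact permutation p = 0.0397). Nap1l5 stood at 1.48% ± 0.452 and 3.78% ± 2.33 (n = 5 each, exact permutation p = 0.0873). Peg10, Nnat and Plagl1 had exact permutation p from 0.159 to 0.889 (n = 5 each). At Peg3 control 2 read 13.95% and each of the other 9 samples read 0%, from 63 to 120 reads per sample. At genes beside paternally methylated regions, the lower end of Meg3 stood at 6.47% ± 2.79 and 6.01% ± 1.16 (n = 5 each, exact permutation p = 0.746). The lower end of Rasgrf1 (chromosome 9, 89908508 to 89910008) stood at 0.829% ± 0.203 and 0.481% ± 0.222, with adjusted p = 0.317 (n = 5 each, exact permutation p = 0.0238). Neither it nor Zrsr1 passed the adjusted threshold of 0.05. A single region could not have passed it alone, since the smallest exact p of 0.00794 exceeds it once adjusted over 16 regions.

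Ribosomal DNA, the repeated genes of ribosomal RNA, was read at the Rn18s-rs5 record (chromosome 17, 39846354 to 39848202). It stood at 19.4% ± 5.03 in control and 16.5% ± 2.75 in arsenic sperm over 213 cytosines (n = 5 each, exact permutation p = 0.341). The difference was -2.89 points, and -0.729 without control 3, which read 28.1%. In the 1 kb windows with the widest gap between 1 sample and all others, chosen after their values were seen, that sample was arsenic 4. They lay at the pseudoautosomal boundary of the sex chromosomes, in Gm52481 on Y (90744001 to 90745000) and in Mid1 on X (169987001 to 169988000). Arsenic 4 read 28.04% in the first, where the other 9 samples read 66.9 to 81.7%, and 7.96% in the second, where they read 39.7 to 56.6%.

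**Figure D3:**
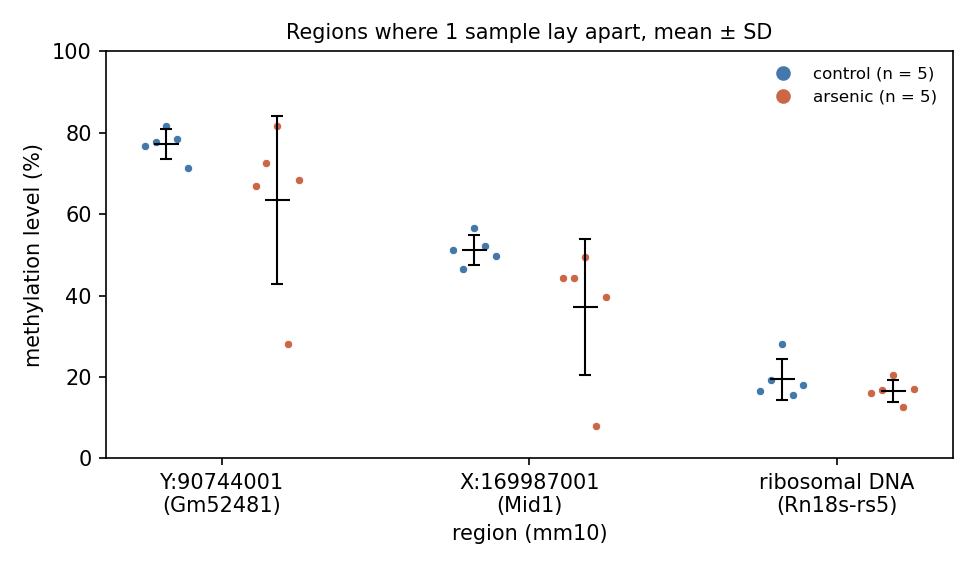
Methylation level in percent of the boundary windows in Gm52481 and Mid1 and of ribosomal DNA; points are samples, bars and whiskers the mean and SD of each group (n = 5). Arsenic 4 lies at 28.04% and 7.96% in the boundary windows, and control 3 at 28.1% in ribosomal DNA.

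At single CpG sites no difference between arsenic and control sperm passed the threshold. The moderated quasi-binomial test of 563011 sites with means from 5 to 95% called 0 sites, at an adjusted p under 0.05 and at least 10 points. At an unadjusted p under 0.05 there were 29953 sites, 5.32% of those tested, 15093 higher and 14860 lower in arsenic sperm. On simulated data the same test gave an unadjusted p under 0.05 at 5.84% of unchanged sites, so 5.32% is no excess. Limma called 0 sites (28272 at an unadjusted p under 0.05), and logistic regression with no overdispersion called 12933. The groups did not overlap at 0.758% of tested sites, 0.86% of windows of 1 kb and 0.841% of gene-end windows, where chance gives 0.794%. On simulated data the test recovered 1.5% of sites changed by 10 points, 21% by 20 and 50.5% by 30. Most changes of 10 points at single sites would therefore not have been detected with these samples. All sizes of change were placed in the same simulated table and adjusted together, so a few lone changes would be recovered less often. The same limit holds for the simulated windows and gene ends below.

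The smallest adjusted p of a site was 0.106, at position 66670219 of chromosome 3, outside gene records. It stood at 66.6% ± 17.1 in control and 97.2% ± 2.8 in arsenic sperm from 18 to 70 reads (n = 5 each), and control 4 read 36.5%. The next 4 sites in the higher direction had adjusted p from 0.346 to 0.701. Position 95313196 of chromosome 8, in the testis-expressed gene Tepp, read 0% in every control sample and 16.3% ± 6.47 in arsenic sperm. Position 176690234 of chromosome 1 stood at 23.9% ± 3.44 and 49.96% ± 5.59, and position 88041629 of chromosome 15 at 7.78% ± 2.68 and 25.6% ± 2.93. Position 32524379 of chromosome 13 stood at 89.1% ± 3.88 in control and at 100% in every arsenic sample. The 5 sites of smallest p in the lower direction had an adjusted p of 0.701. One lay in Maml3, a coactivator of Notch signalling (chromosome 3, position 51917731), at 97.6% ± 2.19 in control and 81.001% ± 5.1 in arsenic sperm. Position 58239658 of chromosome 11, in the long noncoding RNA Gm51898, stood at 14.3% ± 8.84 and 0.455% ± 1.02. Position 21299512 of chromosome 17, 11859 bp from the vomeronasal receptor gene Vmn1r236, stood at 43.6% ± 5.21 and 20.4% ± 7.34. Position 35327392 of chromosome 10 stood at 83.2% ± 5.23 and 60.8% ± 2.81, and position 12430173 of chromosome 3 at 96.04% ± 4.61 and 73.5% ± 7.52.

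**Figure D4:**
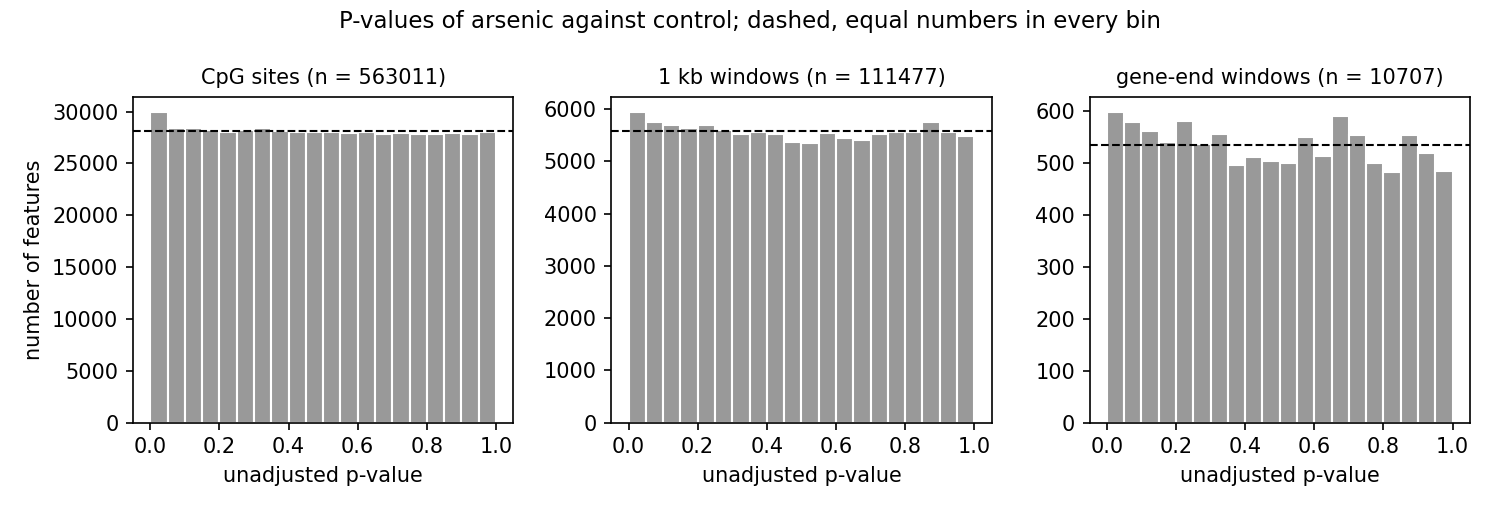
Number of features by unadjusted p of arsenic against control, for CpG sites, 1 kb windows and gene-end windows; the dashed line marks equal numbers in every bin. The first bin holds 5.32% of sites, 5.33% of windows and 5.59% of gene ends. For unchanged simulated features the shares under 0.05 were 5.84%, 5.41% and 5.75%.

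Windows of 1 kb, which asked whether neighbouring sites shift together, gave no call either. The moderated quasi-binomial test called 0 of 111477 windows, with a smallest adjusted p of 0.707 and 5942 windows at an unadjusted p under 0.05. Limma called 0 windows (5741 at an unadjusted p under 0.05), edgeR 0 (5390), and logistic regression with no overdispersion 3381. The window of smallest p (chromosome 10, 62549001 to 62550000), 8470 bp from the kinesin-binding protein gene Kifbp, stood at 35.6% ± 3.37 in control and 49.8% ± 2.4 in arsenic sperm (n = 5 each). A window in Ajap1, an adherens junction protein gene (chromosome 4, 153419001 to 153420000), stood at 90.2% ± 1.43 and 95.6% ± 1.23. A window 23020 bp from Lig4, a DNA ligase of end joining, stood at 80.3% ± 1.9 and 86.4% ± 1.35. Windows outside gene records that start at 88584001 of chromosome 16 and 107290001 of chromosome 6 stood 9.67 and 7.03 points higher in arsenic samples. In the lower direction, a window in the long noncoding RNA 4930548K13Rik (chromosome 4, 26646001 to 26647000) stood at 38.4% ± 1.998 and 29.3% ± 2.44. The window around position 12430173 of chromosome 3 stood at 80.6% ± 1.9 and 70.4% ± 2.29. A window in 2900026A02Rik and 4833439F03Rik (chromosome 5, start 113138001) differed by -3.88 points, and those that start at 58263001 of chromosome 18 and 168847001 of chromosome 2 by -6.75 and -4.33. On simulated data 11% of windows changed by 5 points were recovered, 44.5% by 10 and 81% by 20.

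**Figure D5:**
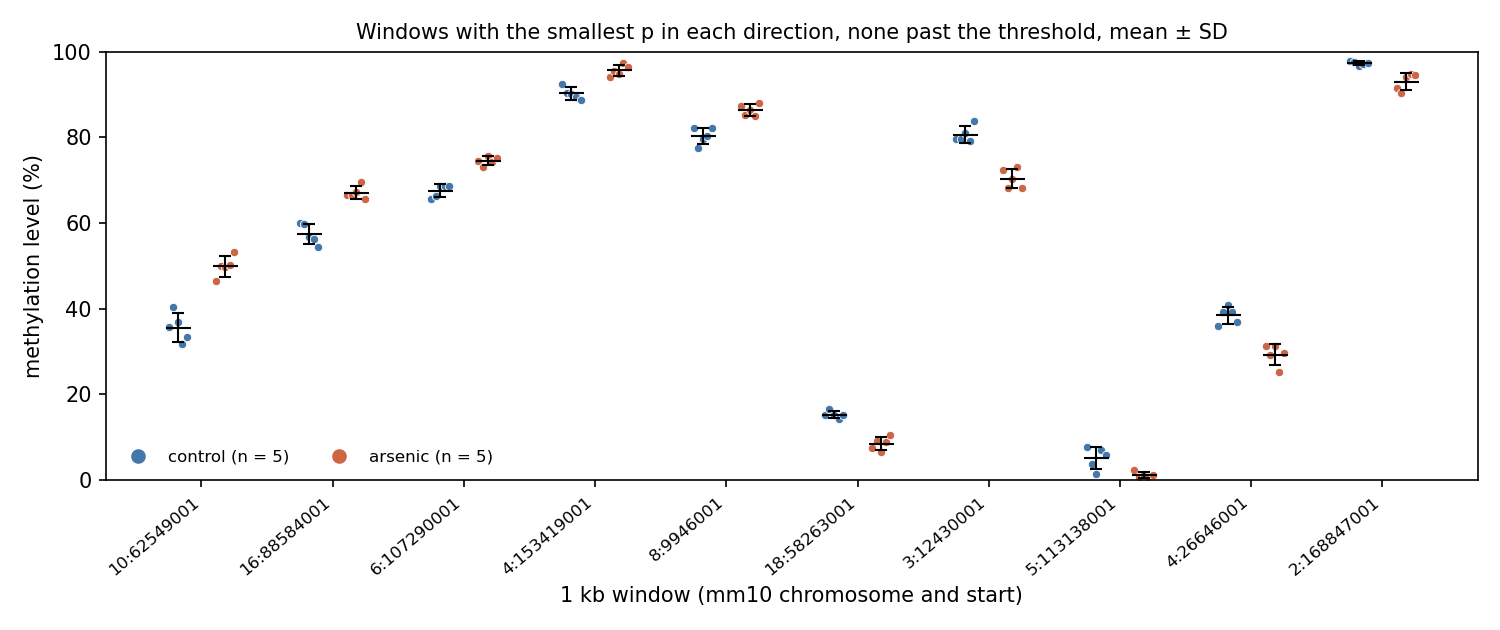
Methylation level in percent of the 5 windows of smallest p in each direction, by mm10 chromosome and start; points are samples, bars and whiskers the mean and SD of each group (n = 5). The first 5 are higher and the last 5 lower in arsenic samples, and all have an adjusted p of 0.707.

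Gene-end windows, tested in place of promoters, gave 0 calls among 10707 by the moderated quasi-binomial test. The smallest adjusted p was 0.615, and 598 had an unadjusted p under 0.05. Limma called 0 gene ends (585 at an unadjusted p under 0.05), and logistic regression with no overdispersion 440. Lrrc15, a membrane protein gene (chromosome 16, 30282754 to 30284254), stood at 33.8% ± 2.5 in control and 26.7% ± 2.34 in arsenic sperm over 37 cytosines (n = 5 each). Arfgef2, an exchange factor of vesicle traffic, stood at 42.04% ± 5.35 and 28.4% ± 4.64. The long noncoding RNAs Gm7967 and Gm39271 differed by -6.14 and -19.4 points. In the higher direction Fcor, a corepressor of Foxo1, stood at 7.21% ± 0.742 and 11.05% ± 1.49, and the long noncoding RNA Gm52104 at 95.8% ± 1.46 and 98.9% ± 0.74. The pseudogene Gm3188 stood at 36.9% ± 8.95 and 59.2% ± 4.69, and Gm46081, whose window overlaps that of Gm8197, at 20.1% ± 4.78 and 33.3% ± 5.66. On simulated data 24.5% of gene ends changed by 5 points were recovered, 65% by 10 and 91.5% by 20.

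The 14 gene lists asked whether pathways of the germline, of imprinting or of arsenic handling shifted as groups. Each member was read at the end of its record with more covered cytosines, which may not be its promoter. None passed the exact permutation test after adjustment over the lists, with a smallest adjusted p of 0.667, and no member was called over all gene ends. Adjusted over the list alone, 1 member of 1 list was called, the zinc finger gene Zfp872 (chromosome 9, 22187166 to 22188666). It stood at 38.4% ± 4.57 in control and 27.5% ± 1.13 in arsenic sperm, with an adjusted p of 0.00718 adjusted over the list alone of 45 tested members and 0.615 over all gene ends in the moderated quasi-binomial test. Zfp995 stood at 14.8% ± 4.27 and 22.6% ± 3.5. The zinc finger genes together stood at 7.74% ± 0.205 and 7.75% ± 0.0885 over 245 members (n = 5 each, exact permutation p = 0.968).

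Genes of sperm and spermatid proteins stood at 54.98% ± 0.305 and 54.4% ± 0.494 over 18 members (n = 5 each, exact permutation p = 0.0635). H1f7, the spermatid linker histone, stood at 7.17% ± 1.43 in control and 3.999% ± 1.19 in arsenic sperm, with an adjusted p of 0.0326 adjusted over the list alone and 0.0163 in the histone list, but a difference under 5 points. Izumo1, the sperm protein that binds the egg, stood at 97.4% ± 1.37 and 95.8% ± 0.812. Histone genes stood at 1.4% ± 0.19 and 1.36% ± 0.156 over 48 members, whose windows hold 36 distinct sets of cytosines (n = 5 each, exact permutation p = 0.714). Germline genes whose promoters are methylated in somatic cells stood at 9.8% ± 0.275 and 9.81% ± 0.268 over 18 members (n = 5 each, exact permutation p = 0.881). In that list the testis tubulin gene Tuba3b stood at 4.86% ± 1.23 and 2.6% ± 0.822, with an adjusted p of 0.0473 adjusted over the list alone and a difference under 5 points, and the germ cell gene Dazl at 5.06% ± 1.86 and 2.6% ± 1.25. Maternally methylated imprinted genes stood at 6.22% ± 0.622 and 6.51% ± 0.599 over 19 members (n = 5 each, exact permutation p = 0.468), with an adjusted p of 0.0293 for Zrsr1 adjusted over the list alone, again under 5 points. Over all gene ends H1f7, Tuba3b and Zrsr1 each had an adjusted p of 0.695 in the moderated quasi-binomial test. Markers of somatic cells that a sperm preparation could hold stood at 40.2% ± 0.528 and 39.96% ± 1.24 over 20 members (n = 5 each, exact permutation p = 0.69), and 0 of 11 tested members had an unadjusted p under 0.05.

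The oxidative stress genes stood at 10.6% ± 0.416 and 10.2% ± 0.283 over 21 members (n = 5 each, exact permutation p = 0.151). Of its 7 tested members 3 had an unadjusted p under 0.05 in the quasi-binomial test, as had 5.59% of all tested gene ends. These 3 were all lower in arsenic sperm, and 0 were called, with adjusted p from 0.062 to 0.0938 adjusted over the list alone. Txnrd2, a mitochondrial thioredoxin reductase, stood at 3.65% ± 0.464 and 2.5% ± 0.365. Gpx1, a glutathione peroxidase, stood at 16.7% ± 2.59 and 12.3% ± 2.32, and Sod3, the extracellular superoxide dismutase, at 90.2% ± 3.57 and 84.8% ± 2.69. Genes of arsenic methylation, one-carbon metabolism and arsenic transport stood at 6.55% ± 0.15 and 6.57% ± 0.213 over 18 measured of 27 listed members (n = 5 each, exact permutation p = 0.889). As3mt, the arsenic methyltransferase gene, was not among those measured, and only 4 members could be tested singly. Among them the arsenite channel gene Aqp9 stood at 96.6% ± 1.38 and 96.9% ± 0.256 and the glutathione transferase gene Gsto1 at 2.83% ± 1.02 and 2.86% ± 0.83. Liver tumour genes stood at 1.48% ± 0.264 and 1.2% ± 0.191 over 23 members (n = 5 each, exact permutation p = 0.0952). The beta-catenin gene Ctnnb1, the only member that could be tested singly, stood at 11.1% ± 3.79 and 8.2% ± 2.36.

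Genes of the DNA methylation machinery stood at 11.5% ± 0.588 and 11.1% ± 0.309 over 19 measured of 28 listed members (n = 5 each, exact permutation p = 0.254). The methyltransferase genes Dnmt1 and Dnmt3a were not among those measured. Dnmt3l, a cofactor of germline DNA methylation, stood at 71.3% ± 3.66 and 65.8% ± 5.21. The piRNA pathway stood at 25.8% ± 0.516 and 26.1% ± 0.603 over 18 members (n = 5 each, exact permutation p = 0.484), with the trimming nuclease gene Pnldc1 at 51.8% ± 5.9 and 59.3% ± 5.33. Hox cluster genes stood at 4.71% ± 0.276 and 4.62% ± 0.387 over 37 members (n = 5 each, exact permutation p = 0.659), with Hoxb6 at 5.71% ± 2.2 and 2.87% ± 1.45 and Hoxd4 at 95.8% ± 0.938 and 94.1% ± 1.41. Clustered protocadherin genes stood at 7.42% ± 0.912 and 7.28% ± 1.48 over 36 members (n = 5 each, exact permutation p = 0.857). Many of them share an end of their cluster, so that their windows hold 20 distinct sets of cytosines, and the difference of -0.136 points became 0.38 with each set counted once. Olfactory and vomeronasal receptor genes stood at 61.1% ± 0.238 and 61.1% ± 0.456 over 72 members (n = 5 each, exact permutation p = 0.984), with Olfr564 at 94.8% ± 2.36 and 88.3% ± 5.43. In the quasi-binomial test adjusted over each list alone, the adjusted p was 0.143 for Dnmt3l, 0.469 for Pnldc1, 0.181 for Hoxb6, 0.197 for Hoxd4 and 0.813 for Olfr564.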

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

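The tests of conversion at sites with means under 1% and over 98% were chosen only after the results had been seen. In 256 groups of 5 samples, 12 times a sample lay apart from the other 4 by more than 0.71 of the group's range. Of these, 2 were at the pseudoautosomal windows, which were chosen because 1 sample stood apart. Chance gives about 1 in 20 groups, and the groups not chosen that way had 10 against 12.6 by chance.

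Arsenic 4 lay apart at the pseudoautosomal boundary, with 28.04% in the window in Gm52481 (other 9 samples 66.9 to 81.7%) and 7.96% in the window in Mid1 (39.7 to 56.6%). A change in the number of copies was tested by read depth, where arsenic 4 had 11.98 CPM (reads scaled by the sample's total) in the first window and 15.5 in the second, where its rank was 2 of 10 from the lowest. The other 9 samples ran from 7.44 to 45.2 and from 10.8 to 61.8, too wide a range to exclude a loss or gain, so a change in copies stays open. A loss of methylation across the library as large as that in these windows predicts 35.8% at sites with a mean over 98% in the other 9 samples. Arsenic 4 read 97.96% there, and each of the others, at sites chosen without it, 97.99 to 98.1%. The other 4 arsenic samples did not share the low levels, and whether exposure or a sequence variant of this animal or pool may be the source was not tested.

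Control 3 lay apart in ribosomal DNA, with 28.1% where the other control samples read 15.6 to 19.2%. Incomplete bisulfite conversion across the library that raised it that far predicts 14.2% at sites with a mean under 1% in the other 9 samples. Control 3 read 0.6999% there, and each of the others, at sites chosen without it, 0.556 to 0.709%. Conversion within ribosomal DNA alone was not tested. The number of ribosomal DNA copies was tested by the share of reads on the record over 10 samples, with Spearman's rho 0.0545 (permutation p = 0.892), Pearson's r 0.0846 (permutation p = 0.806) and r 0.246 without the 2 samples farthest from the median share. The interval of rho from -0.596 to 0.661 leaves a sizeable relation open, which the bound set in advance, a p alone, did not allow for, so copy number cannot be told apart from other sources. No explanation from the exposure was tested, since this is a control sample. Arsenic 3, of the same replicate number, read 20.4% in ribosomal DNA, the highest of the arsenic samples. Whether a batch shared by that number plays a part was not tested.

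Among the others were these. The mean of the Hox cluster genes was 5.19% in control 3 and 4.53 to 4.71% in the other control samples. Peg3 read 13.95% in control 2 and 0% in the others, and Plagl1 6.73% in control 1 and 0 to 1.48% in the others. Position 66670219 of chromosome 3 read 36.5% in control 4 (69.4 to 77.8% in the others), position 35327392 of chromosome 10 92.2% in control 3 (78.6 to 82.5%), and position 58239658 of chromosome 11 2.27% in arsenic 1 (0% in the others). Tuba3b read 1.17% in arsenic 3 (2.65 to 3.18%) and Aqp3 1.35% in control 4 (2.997 to 3.64%).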

How the results depend on the processing

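The alternatives with halved reads, with both ends of each gene record, with shared gene ends counted once and without control 3 (the last within the ranges for leaving out samples) were chosen only after the data had been seen. The adjusted p planned for lists and regions was applied as the threshold in these comparisons after results at the unadjusted p had been seen. At the unadjusted p, the lower end of Rasgrf1 lost the threshold in 3 settings (exact p 0.0556 to 0.127) and that of Zrsr1 in 10 (0.0556 to 0.125), while other lists or regions passed it in 11, among them sperm proteins in 4 (0.0317 to 0.0476). At the adjusted p no list or region passed in any setting run. That outcome was largely fixed by the design, so it is no sign of stability. Over 14 lists or 16 regions a single one at the smallest exact p of 0.00794 cannot pass, and the smallest sign-flip p of the replicate block is 0.0625. Counts of called sites, windows and gene ends stayed at 0 with limma, dispersion of each feature alone, 20 reads, the upper coverage limit and no filter on the mean. Merged strands, autosomes and other limits of difference, run for sites alone, and edgeR, other window sizes and a minimum of 5 sites, run for windows alone, also gave 0, as did gene ends from 500 bp either side. Logistic regression with no overdispersion called 6535 sites higher and 6398 lower in arsenic sperm, 1703 and 1678 windows, and 191 and 249 gene ends, since it takes reads as replicates. With halved reads it called 60 and 76 sites, 579 and 613 windows, and 103 and 132 gene ends. The calls named next were chosen after their values were seen. Gene ends from 2000 bp outside gave 1 lower call, Rerg (chromosome 6, 137169996 to 137172496, -9.78 points, adjusted p = 0.0359). Leaving out samples gave 0 to 1 higher sites and 0 to 1 lower windows. Without control 2 the site was position 66670219 of chromosome 3 (33.2 points, adjusted p = 0.0498), and without control 4 the window was in Mtcl1 (chromosome 17, 66343001 to 66344000, -9.08 points, adjusted p = 0.041). Over the alternatives that allow overdispersion, the smallest adjusted p ran from 0.0498 to 1 for sites, 0.041 to 0.99998 for windows and 0.0359 to 0.985 for gene ends. The cause of these calls was not tested.

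Deviations from the group mean in 1 kb windows showed no pairing by replicate number. They correlated by -0.0305 to 0.0287 between same-numbered samples and by -0.0525 to 0.0715 between others. Of 5 control samples, 1 correlated best with its own number. Mitochondrial levels did run alike by number. Control 1 to 5 read 1.66, 1.5, 3.38, 2.32 and 1.91% there, and arsenic 1 to 5 read 1.49, 1.66, 3.37, 2.32 and 2.09%. In ribosomal DNA number 3 was highest and number 4 lowest in both groups, but on Y control 3 and arsenic 2 were highest. Whether samples of 1 number share a batch or source stays open. The replicate block gave 0 called sites, windows and gene ends (30204, 6075 and 607 at an unadjusted p under 0.05) and a mean difference of -0.0155 points (exact sign-flip p = 0.938, smallest possible 0.0625).

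Some differences changed sign, none of them past the threshold in either setting, and the cause was not tested. With shared gene ends counted once the difference was 0.38 points for protocadherin genes. With both gene ends they were -0.166 points for arsenic metabolism genes and -0.0516 for zinc finger genes. With 20 reads they were -0.23 for germline genes, 0.179 for olfactory and vomeronasal genes and -0.0295 for zinc finger genes. With weighting by reads they were -0.00828 for the mitochondrial genome, -1.06 for germline genes, -2.05 for the piRNA pathway and -0.294 for zinc finger genes. Leaving out each sample gave differences of -0.0847 to 0.0405 over all sites, -0.0831 to 0.0419 on autosomes, -0.117 to 0.0609 on X, -0.493 to 0.311 on Y and -0.263 to 0.339 on the mitochondrial genome. Sites under 20% gave -0.0507 to 0.0378, from 20 to 80% -0.409 to 0.265 and over 80% -0.0593 to 0.0286. Lists gave -0.106 to 0.14 (olfactory and vomeronasal), -0.0677 to 0.116 (germline), -0.206 to 0.0302 (Hox), -0.529 to 0.361 (protocadherin), -0.11 to 0.00653 (histone), -0.074 to 0.0605 (zinc finger), -0.042 to 0.0652 (arsenic metabolism) and -0.661 to 0.16 (somatic cells). Regions gave -0.771 to 0.00253 (H19 control region), -0.492 to 0.336 and -1.65 to 4.17 (lower and higher end of H19), -1.33 to 0.427 (Meg3), -0.318 to 0.666 (Airn), -3.42 to 0.00073 (upstream of Rasgrf1) and -0.504 to 1.75 (Plagl1). Gene ends gave -0.231 to 0.623 (Aqp9), -0.781 to 0.362 (Mthfd1), -0.226 to 0.364 (Gsto1), -1.76 to 0.187 (H2ac1 and H2bc1, whose overlapping windows hold the same cytosines) and -0.761 to 0.211 (Aqp3). A minimum of 5 reads changes nothing in a table with at least 10, and repeats and annotation classes were not run. What depth alone limits was not tested, since the simulated data kept the coverage and spread of these samples.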

Other observations

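The test of sequencing depth, the halving of reads and the gap of 20 points, 1 of 4 gaps looked at, were chosen only after results had been seen, as were the genes named next. Among sperm protein genes 10 of 18 measured gene ends averaged over 80% and 8 under 20%. Prm1, a protamine that packs sperm DNA, averaged 94.2% ± 4.16, transition protein gene Tnp2 93.8% ± 2.99 and Tnp1 4.8% ± 2.69 (SD, n = 10). Catsper1, a sperm calcium channel gene, averaged 98.1% ± 0.781 and Catsper2 0.638% ± 0.369 (SD, n = 10). Of the germline genes methylated in somatic cells 16 of 18 measured gene ends averaged under 20%, and the higher end of Tex19.1 averaged 97.3% ± 0.801 over 8 cytosines (SD, n = 10). In gene-end windows as a whole 84.4% of cytosines had a mean under 20%, so that count is no sign of a trait of these genes. The gene records carry no strand, so the ends read here, those of the sperm protein genes included, may not be promoters.

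Logistic regression with no overdispersion called 12933 sites, and 48 of 100 splits, the real one included, gave as many, with 15419 in the highest other split, so chance could not be excluded. With halved reads it called 136 sites (1.05% as many), under the tenth part, a bound for overlapping mates counted as separate reads that was set after the full count and before the halved one was seen, but 1192 windows against 3381 (35.3%) and 235 gene ends against 440 (53.4%). Halving also lowers the power to find real differences, so this explanation stays open. For the moderated test, which called 0 sites, windows and gene ends, all 100 of 100 splits had to give as many, so that count tests nothing, and the highest other split called 1 site, 1 window and 2 gene ends. At an unadjusted p under 0.05, 53 splits had as many sites, 46 as many windows and 25 as many gene ends.

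A hypothesis was that arsenic samples vary more from each other. Among 135102 windows with 100 reads in every sample, 33 had 1 sample at least 20 points from all others, 4.4 ± 1.82 per control and 2.2 ± 1.79 per arsenic sample (SD, n = 5 each, exact permutation p = 0.111). Gaps of 15, 25 and 30 points gave exact p of 0.77, 1 and 1. The SD was larger in the arsenic group in 52.2% of tested windows, and 87 of 99 other splits, each measured on its side with more arsenic samples, lay below that, with 54.3% in the highest. Fewer than 95 lay below, the bound set in advance, so neither test found a wider spread in arsenic samples.

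Partly methylated sites had lower mean levels in samples of higher median coverage, with Spearman's rho -0.915 (permutation p = 0.00051, adjusted p = 0.00102 over 2 relations) and Pearson's r -0.894 (permutation p = 0.00032, adjusted p = 0.00064) over 10 samples. Pearson's r was -0.822 without the 2 samples farthest from the median coverage. Sequencing depth may therefore add to the spread between samples at these sites, but other traits of the libraries were not tested. The adjustment does not cover the choice of this stratum, the only one correlated with coverage. Over all sites control 3, of lowest median coverage (28), read 52.3%, and control 4, of highest (45), 51.8%, a relation that was not tested.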
